A study of Mus musculus with 12 samples.

How the data were processed

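Total RNA from kidneys of fasted mice was sequenced by the authors with a stranded total RNA library kit, per the labels. The 12 samples form 4 groups of 3: wild type with vehicle, wild type with GW4064, FXR knockout with vehicle and FXR knockout with GW4064. Groups were taken from the sample labels, and no sample was left out. The authors deposited 1 table of genes per sample, with chromosome, start, end, coverage, FPKM and TPM, and per the submitters' processing notes HISAT2, StringTie and Cufflinks were used on mm10. Versions, the role of each tool and the annotation are not given in the sources used here.

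The deposited TPM values were made by the authors by dividing by gene length and scaling each sample to a total of 1000000. The deposited FPKM values are a constant multiple of TPM within each sample, and were used as an alternative and for depth. The deposited coverage signal was taken as the mean number of reads over each base of a gene, and was used for depth only. No read counts were used here, so tests made for counts were not applied. Entries of 1 gene identifier (113 to 142 identifiers per sample had several) were summed. Of 24532 identifiers, 24462 had a symbol in the RefSeq gene table of GRCm38.p6, and coordinates were taken from the deposited tables. No gene of the mitochondrial chromosome was present.

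Depth was derived from the deposited values. A gene covered by 1 read pair holds 202 bases, and the FPKM of such genes gave the number of read pairs per library. Spread within groups, as the median SD of log2 values, was 0.0933 in wild-type vehicle, 0.0897 in wild-type GW4064, 0.107 in knockout vehicle and 0.105 in knockout GW4064 libraries.

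Tests were run in R 4.3.3 with limma 3.58.1, and tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. TPM values were transformed as log2(TPM + 0.5), so fold changes of genes at low TPM are drawn toward 0. Genes with at least 1 TPM in at least 3 samples were kept, 14488 in all. A linear model with 1 mean per group was fitted to all 12 samples with limma, with moderated variances that follow the mean level. The 5 comparisons were GW4064 against vehicle in wild type, the same in the knockout, knockout against wild type on vehicle, the same under GW4064, and the interaction. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Errors beside TPM are SD and errors beside log2 changes are standard errors. An exact permutation test of 3 samples against 3 cannot give a two-sided p under 0.1, and none was used.

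Gene lists for pathways, cell types and neighboring tissues were fixed before the data were examined, 39 in all, of which 37 had at least 3 tested members. They were written from general knowledge, and 44 genes are on more than 1 list. Each list was tested with camera (limma) at a preset correlation of 0.01, again with an estimated correlation, and with fry, and p-values were adjusted over the 37 lists of a comparison. Of the 37 lists, 5 were called for GW4064 in wild type, 7 for GW4064 in the knockout, 14 for each genotype comparison and 7 for the interaction, and 0 in each comparison with an estimated correlation. For members, counts over all genes and counts adjusted over the list alone are given.

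Genes to be named were set by a rule before the data were examined. They are 11 fixed genes, and, per comparison, up to 10 called genes per direction with the largest log2 change among those with a mean of at least 5 TPM in the groups compared, no overlap between the groups (not required for the interaction) and a symbol that is not a gene model. For each list the 2 members of lowest p in each direction could be named. Members of a list named because their count was 5 or fewer, and Nnt, Cfd and the genes on shared loci, were chosen after their values were seen. Many genes the rule gives are not reported here.

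The fit was tested on simulated data with the means and residual spread of the real genes, 200 changed genes and 20 runs per comparison. For GW4064 in wild type it recovered 59.4%, 84.5% and 96.1% of genes changed by 0.5, 1 and 2 on the log2 scale, with 4.11% false calls. For GW4064 in the knockout it recovered 59.0%, 83.8% and 96.4%, with 5.01% false calls. For the overlap of comparisons that share the wild-type vehicle libraries, 100 data sets with no change were simulated. Alternatives were other pseudocounts, filters, scalings, units, variance models, sample weights, samples in the fit, a block, and leaving out each library. Restriction to protein-coding genes and a fat marker score (mean log2 value of Adipoq, Plin1, Cfd and Cidec) as a covariate were added after seeing the data.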

Results

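Total RNA from the kidneys of fasted mice was sequenced in 12 libraries. Wild-type mice (C57BL/6) and mice carrying a targeted disruption of Nr1h4 received vehicle or GW4064. Nr1h4 is the gene of the farnesoid X receptor (FXR, a nuclear receptor for bile acids), and GW4064 is a synthetic FXR agonist. The labels give a treatment time of 6 h for the GW4064 libraries and none for the vehicle libraries. Each of the 4 groups (wild-type vehicle, wild-type GW4064, knockout vehicle, knockout GW4064) held 3 libraries. The series title concerns FXR, cisplatin-induced kidney injury and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. None of the libraries analysed here was labelled as given cisplatin. The ratio of deposited coverage to FPKM gave 2.86 to 4.27 mapped gigabases per library, and genes covered by 1 read pair gave 14.1 to 21.2 M (mega) read pairs. Between 16693 and 17186 of 24532 genes had a value above 0. Kap, an androgen-regulated proximal tubule gene, was the most abundant transcript in each library (4.79% to 6.40% of the TPM total). Correlations of log2 values were 0.982 to 0.988 within groups and 0.970 to 0.987 between groups, and no pair of libraries held identical values. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples.

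The disrupted gene was examined first. Nr1h4 (Entrez Gene 20186, protein-coding, chromosome 10, 89454234 to 89533622, mm10) measured 217, 267 and 249 TPM in the wild-type vehicle libraries and 189, 206 and 242 TPM in the wild-type GW4064 libraries. The knockout vehicle libraries gave 120, 116 and 113 TPM, and the knockout GW4064 libraries gave 105, 131 and 134 TPM. Each of the 6 knockout libraries was thus below each of the 6 wild-type libraries. The log2 difference, knockout minus wild type, was -1.06 ± 0.11 (SE) on vehicle and -0.78 ± 0.11 under GW4064 (limma, Benjamini-Hochberg adjusted p = 1.9e-04 and 4.4e-04, n = 3 per group). The allele removes part of the gene, and a value for the whole gene does not tell intact from truncated transcripts.

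The first question was which kidney transcripts differ after the agonist where the receptor gene is intact. Both subunits of the basolateral bile acid and steroid exporter rose steeply. Slc51a (Entrez Gene 106407, chromosome 16, 32475578 to 32487879) went from 42.1 ± 5.86 TPM on vehicle to 457 ± 49.2 TPM (SD, n = 3), a log2 change of 3.43 ± 0.12 (SE). Slc51b (Entrez Gene 330962, chromosome 9, 65412753 to 65422773) went from 49.2 ± 6.63 to 345 ± 39.4 TPM, a log2 change of 2.80 ± 0.13. Tm4sf4 is a tetraspanin-family membrane protein gene (chromosome 3, 57425410 to 57441675). Its log2 change of 3.80 ± 0.31, from 1.37 ± 0.339 to 26.1 ± 8.55 TPM, was the largest among the called genes that the rule named. In all 3 genes each GW4064 library lay above each vehicle library, with adjusted p = 9.2e-08, 6.5e-07 and 4.7e-05 (limma, Benjamini-Hochberg).

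**Figure D1:**
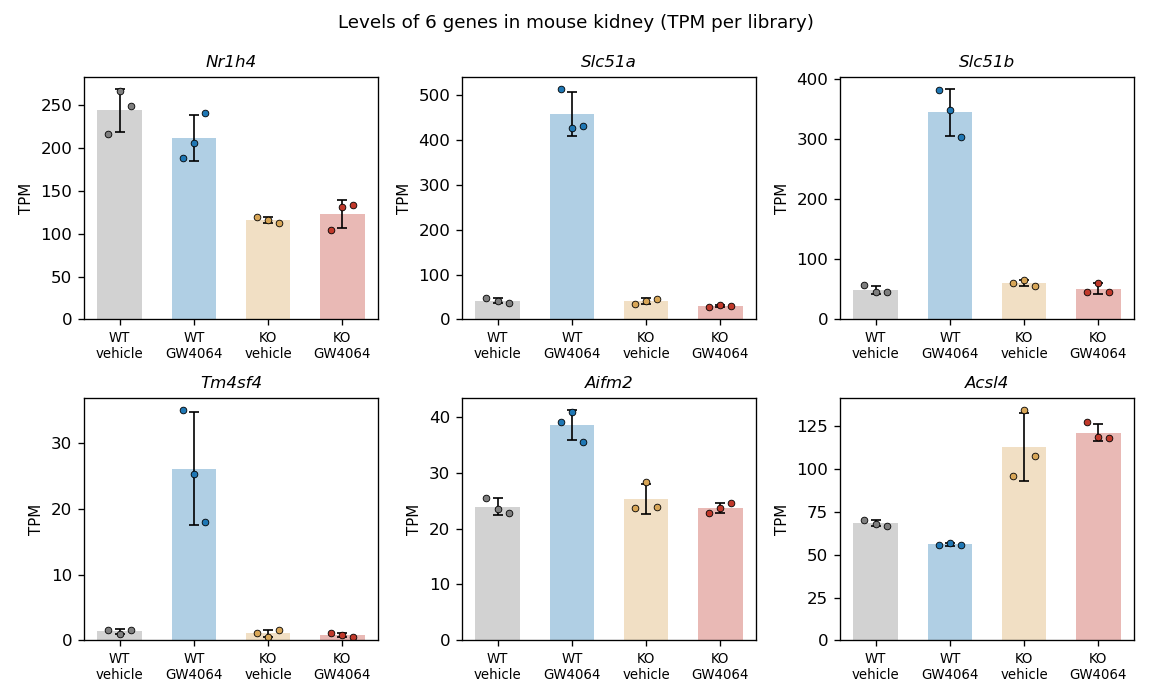
Expression of 6 genes in TPM (vertical axis) in the 4 groups (horizontal axis), where points are single libraries, bars are group means and error bars are the SD of 3 libraries. Slc51a, Slc51b and Tm4sf4 stand above the other groups in wild type with GW4064 (means 457, 345 and 26.1 TPM), Aifm2 is highest there (38.5 TPM), and Nr1h4 is lower in both knockout groups.

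Across 14488 genes tested, 696 differed after GW4064 in wild type (limma, adjusted p under 0.05), 360 higher and 336 lower, and 81 of them by at least 2-fold (50 higher, 31 lower). Further genes among the largest increases were Cyp27b1, the renal 1-alpha-hydroxylase that activates vitamin D (2.42 ± 0.56), the fibrinogen gene Fgb (2.30 ± 0.22), Tstd2 (2.05 ± 0.10), the galactosyltransferase gene B4galt5 (1.85 ± 0.10, 33.9 ± 0.933 to 123 ± 7.31 TPM), Etnppl, which breaks down phosphoethanolamine (1.85 ± 0.26), the long noncoding transcript Mkln1os (1.74 ± 0.22) and complement C3 (1.68 ± 0.20). Large decreases were measured in Noct, a rhythmic phosphatase gene (-1.64 ± 0.31), the solute carriers Slc16a14 (-1.58 ± 0.23), Slc13a2, the apical citrate transporter (-1.37 ± 0.18) and Slc25a25, a mitochondrial ATP-magnesium/phosphate carrier (-1.36 ± 0.25), Cck (-1.30 ± 0.28), Bcl6 (-1.27 ± 0.29), Prob1 (-1.20 ± 0.18), Tnn (-1.10 ± 0.17) and Lpin1, a phosphatidate phosphatase (-1.06 ± 0.20). Pck1, the gluconeogenic enzyme PEPCK, was at 7702 ± 745 TPM on vehicle and 3615 ± 766 TPM with GW4064 (log2 -1.11 ± 0.19, adjusted p = 0.00665, limma).

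The count of 696 depended on single libraries. It was 334 without wild-type GW4064 replicate 1, 407 without wild-type GW4064 replicate 2, 390 without wild-type vehicle replicate 3 and 449 without wild-type vehicle replicate 1. Noct and Lpin1 lost their call without wild-type GW4064 replicate 1 (limma adjusted p = 0.0535 for both). Cyp27b1 lost it without any of the 3 wild-type GW4064 libraries, and Cck and Bcl6 without any of 4 libraries each (adjusted p up to 0.111, 0.0894 and 0.12, limma). Cck did so without wild-type vehicle replicates 1 and 3 and GW4064 replicates 1 and 2, and Bcl6 without vehicle replicates 2 and 3 and GW4064 replicates 1 and 3. With median-of-ratios scaling the split was 453 higher and 236 lower.

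Among known FXR target genes, 17 could be tested in wild type. Of these, 5 rose and 2 fell over all genes tested, and 6 rose and 5 fell adjusted over the list alone. Besides the Slc51 pair, the members that rose were Osgin1, an oxidative stress-induced growth inhibitor (1.53 ± 0.27), Abcc2, an apical organic anion pump (0.56 ± 0.12), and Ddah1, which degrades asymmetric dimethylarginine (0.29 ± 0.05). The members that fell were the collecting duct water channel Aqp2 (-0.52 ± 0.10) and kininogen Kng1 (-1.43 ± 0.37). Nr0b2 (SHP), the classical FXR-induced corepressor of liver, stood at only 2.04 ± 0.687 and 2.72 ± 0.0753 TPM, with a log2 difference of 0.38 ± 0.21 that did not pass (adjusted p = 0.364, limma). The list moved up relative to other genes (camera adjusted p = 0.0388, limma), a call lost with an estimated correlation (adjusted p = 0.278) and with median-of-ratios or quantile scaling (adjusted p = 0.0928 and 0.103). It was also lost without knockout vehicle replicate 3 (adjusted p = 0.0649, limma camera).

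Of 18 bile acid and organic anion transport genes, 3 rose (Slc51a, Slc51b, Abcc2) and 1 fell, the multidrug pump gene Abcc4 (-0.68 ± 0.12, 56.6 ± 4.32 to 35.3 ± 3.77 TPM). Adjusted over the list alone, 5 rose and 1 fell. The camera adjusted p was 0.0388, upward, and the adjusted p = 0.278 with an estimated correlation (limma). Quantile scaling also ended this call (adjusted p = 0.209). Abcc2 lost its own call without any of 5 libraries (wild-type vehicle replicates 1, 2 and 3 and GW4064 replicates 1 and 2, adjusted p up to 0.0949), Aqp2 without any of 3 (vehicle replicate 2 and GW4064 replicates 1 and 3, up to 0.0723) and Kng1 without any of 9 of the 12 (all but the 3 knockout vehicle libraries, up to 0.155, limma). The call of Kng1 also ended in 8 of 14 alternatives, median-of-ratios and quantile scaling among them (adjusted p = 0.0569 and 0.0762).

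Of 22 cell cycle genes, 4 rose with GW4064 in wild type over all genes tested and 10 adjusted over the list alone, and none fell. The 4 were the ribonucleotide reductase subunit Rrm2 (0.61 ± 0.11, 6.27 ± 1.12 to 9.75 ± 0.157 TPM), topoisomerase Top2a (0.98 ± 0.21), cyclin Ccna2 (0.97 ± 0.22) and Mki67 (1.02 ± 0.24, 4.21 ± 1.35 to 8.84 ± 0.949 TPM). The upward camera call (adjusted p = 1.5e-08, limma) was lost with an estimated correlation (adjusted p = 0.643). Top2a, Ccna2 and Mki67 each lost their call without wild-type vehicle replicate 2 or 3 or GW4064 replicate 3, and also without GW4064 replicate 1 (Top2a, Mki67) or 2 (Ccna2, Mki67), with adjusted p up to 0.0859, 0.116 and 0.127 (limma). The calls of Ccna2 and Mki67 also ended with no filter on low values and with a block by replicate number. That of Mki67 ended without the variance trend, and those of Top2a and Mki67 with a fat marker score as a covariate.

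Lists of 2 other parts of the organ, the urothelium and the principal cells of the collecting duct, passed downward at the preset correlation. None of 7 urothelial markers was called over all genes, while 3 fell adjusted over the list alone, and the list as a whole moved down (camera adjusted p = 0.0331, limma), with adjusted p = 0.822 with an estimated correlation. Of 12 principal cell markers of the collecting duct, 1 (Aqp2) fell over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0419, downward, limma, and adjusted p = 0.716 with an estimated correlation). The principal cell call was lost without wild-type vehicle replicate 2, GW4064 replicate 1 or GW4064 replicate 3 (adjusted p = 0.191, 0.0823 and 0.0578, limma camera). Fat markers varied between libraries of the same group. Their score, a mean of log2 values, was -0.26, 2.70 and 0.52 in the wild-type GW4064 libraries against 1.99 to 2.30 in the wild-type vehicle libraries. Of 10 fat markers tested, 1 fell, with a list median of -0.74 (camera adjusted p = 0.267, limma, and adjusted p = 0.822 with an estimated correlation). The member that fell was Pck1, which is also on the proximal tubule and gluconeogenesis lists. Without wild-type GW4064 replicate 2 that list passed (adjusted p = 0.00474, limma camera). With the score as a covariate, chosen after seeing the data, 428 genes were called in place of 696, and the urothelial and principal cell lists were not (adjusted p = 0.123 and 0.119).

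Ferroptosis genes were of interest given the series title. Aifm2 (Entrez Gene 71361, chromosome 10, 61715263 to 61739260), which encodes the ferroptosis suppressor FSP1, an oxidoreductase that regenerates reduced coenzyme Q, rose from 23.9 ± 1.46 to 38.5 ± 2.74 TPM with GW4064 in wild type (log2 0.67 ± 0.08, adjusted p = 5.8e-04, limma, n = 3 per group). Of 26 ferroptosis suppressor genes, 5 rose and 1 fell. The other 4 that rose were Gclm, the modifier subunit of glutathione synthesis (0.43 ± 0.05), glutathione reductase Gsr (0.42 ± 0.06), the iron exporter Slc40a1 (0.40 ± 0.08) and the coenzyme Q synthesis gene Pdss2 (0.24 ± 0.06), and Prom2 fell (-0.45 ± 0.10). Adjusted over the list alone, 5 rose and 2 fell. The list as a whole did not pass (camera adjusted p = 0.225 upward, with a median of -0.0004 and a mean of 0.01, limma, and adjusted p = 0.822 with an estimated correlation). The lipid peroxide reductase Gpx4 was at 1236 ± 53.6 and 1212 ± 8.82 TPM, a log2 difference of -0.03 ± 0.05 that did not pass (adjusted p = 0.801), and ferritin heavy chain Fth1 (-0.18 ± 0.08, adjusted p = 0.271) and Acsl4, which esterifies polyunsaturated fatty acids for peroxidation (-0.28 ± 0.09, adjusted p = 0.116), did not pass either (limma). Acsl4 passed when only the 6 wild-type libraries were fitted (adjusted p = 0.00762) and without knockout vehicle replicate 2 (adjusted p = 0.00819, limma). The cystine transporter gene Slc7a11 lay under the expression filter. Of 24 ferroptosis driver genes 1 rose, the transferrin receptor Tfrc (0.46 ± 0.11), and 1 fell, the amino acid transporter Slc1a5 (-0.39 ± 0.06), and 3 and 3 did so adjusted over the list alone. The driver list did not pass (camera adjusted p = 0.768, and adjusted p = 0.822 with an estimated correlation, limma). Of 15 tubule injury markers 1 rose, Plau (0.28 ± 0.06), and 1 fell, the small heat shock protein gene Cryab (-0.88 ± 0.20), and 1 and 1 did so adjusted over the list alone. That list did not pass either (camera adjusted p = 0.78, and adjusted p = 0.948 with an estimated correlation). The injury markers Havcr1 (1.4 ± 0.614 and 3.28 ± 1.01 TPM) and Lcn2 (4.32 ± 1.25 and 4.02 ± 1.39 TPM) did not pass (adjusted p = 0.154 and 0.886, limma). Slc40a1, Pdss2 and Prom2 lost their calls when any of 4, 9 and 5 libraries was left out (adjusted p up to 0.0742, 0.137 and 0.114, limma). For Slc40a1 these were wild-type vehicle replicates 1 and 2 and GW4064 replicates 1 and 2. For Prom2 they were vehicle replicates 2 and 3 and all 3 GW4064 replicates, and for Pdss2 all 6 wild-type libraries, knockout vehicle replicates 1 and 3 and knockout GW4064 replicate 3. Tfrc lost its call without wild-type vehicle replicates 2 and 3 and wild-type GW4064 replicates 1 and 3 in turn, Plau without wild-type vehicle replicate 1 and wild-type GW4064 replicates 2 and 3 and Cryab without wild-type vehicle replicates 1 and 3 and wild-type GW4064 replicates 1, 2 and 3 (adjusted p up to 0.118, 0.083 and 0.107, limma). All 3 calls also ended without the variance trend and with the fat marker score as a covariate.

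The next comparison asked which transcripts differ after the agonist where its receptor gene is disrupted. Slc51a was at 40.8 ± 6.12 TPM on vehicle and 30.7 ± 2.31 TPM with GW4064 in the knockout (log2 -0.40 ± 0.12, adjusted p = 0.278), and Slc51b at 60.3 ± 4.91 and 50.9 ± 8.98 TPM (-0.25 ± 0.13, adjusted p = 0.524, limma). Only 2 genes passed. Slc16a1, the monocarboxylate transporter MCT1, was higher with GW4064 (101.1 ± 10.4 to 169.7 ± 9.24 TPM, log2 0.75 ± 0.10, adjusted p = 0.0492), and Trim7, a ubiquitin ligase gene, was lower (73.6 ± 2.9 to 50.5 ± 2.03 TPM, -0.54 ± 0.06, adjusted p = 0.0176, limma). Aifm2 (-0.09 ± 0.08), Gpx4 (0.06 ± 0.05), Fth1 (0.18 ± 0.08) and Acsl4 (0.12 ± 0.09) did not pass (adjusted p of 0.485 or higher, limma). At an unadjusted p under 0.05 there were 1560 genes, against 2793 in wild type and 724 expected by chance. Neither call held in all removals of a library. Slc16a1 lost its call without any of 9 libraries, all but wild-type GW4064 replicate 2, knockout vehicle replicate 2 and knockout GW4064 replicate 2. Trim7 lost it without wild-type vehicle replicate 2, knockout vehicle replicates 1 and 3 or knockout GW4064 replicates 1 and 3 (adjusted p up to 0.201 and 0.162, limma). The count of 2 became 0 when only the knockout libraries were fitted, 31 without knockout vehicle replicate 2 and 51 without knockout GW4064 replicate 2. It was 0 without wild-type vehicle replicate 2, knockout vehicle replicate 1 or knockout GW4064 replicate 3, and 1 without wild-type vehicle replicates 1 or 3, wild-type GW4064 replicates 1 or 3, knockout vehicle replicate 3 or knockout GW4064 replicate 1.

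In the knockout 7 gene lists were called at a preset correlation of 0.01 and 0 with an estimated correlation, and no member of the 7 was called over all genes. Of 23 targets of NRF2, the main transcription factor of the antioxidant response, 11 rose with GW4064 adjusted over the list alone and 0 over all genes. The lowest p among them belonged to sulfiredoxin Srxn1 (0.47 ± 0.08) and carbonyl reductase Cbr3 (1.12 ± 0.23, 5.43 ± 0.269 to 13 ± 5.25 TPM), neither past the threshold over all genes. The list's camera adjusted p was 1.0e-08, and the adjusted p = 0.243 with an estimated correlation (limma). Of 25 genes of PPAR-alpha and fatty acid oxidation, 4 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 3.2e-06, and adjusted p = 0.602 with an estimated correlation), with the lipid droplet gene Plin2 at 0.57 ± 0.16. Of 26 ferroptosis suppressors, 7 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0277, and adjusted p = 0.608 with an estimated correlation, limma). That call was lost without knockout vehicle replicate 1 or knockout GW4064 replicate 1 (adjusted p = 0.165 and 0.16).

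The lists that moved down in the knockout were nuclear-encoded respiratory chain genes (30 tested, 0 called over all genes and 0 adjusted over the list alone, list median -0.04, camera adjusted p = 1.0e-05, limma), proximal tubule markers and cholesterol synthesis genes. The respiratory chain list did not pass with an estimated correlation (adjusted p = 0.379). Of 24 proximal tubule markers 2 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 4.3e-05, and adjusted p = 0.203 with an estimated correlation), with the phosphate transporter Slc34a1 at -0.30 ± 0.07 and the inositol oxygenase Miox at -0.30 ± 0.08. Of 24 cholesterol synthesis genes 3 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 9.9e-04, and adjusted p = 0.159 with an estimated correlation), with Mvd at -0.32 ± 0.08. The immune cell list passed narrowly downward (16 tested, 0 called over all genes and 0 adjusted over the list alone, camera adjusted p = 0.0491, and adjusted p = 0.693 with an estimated correlation). Of 13 alternatives 7 ended that call. It was also lost without wild-type vehicle replicate 3, wild-type GW4064 replicates 2 or 3, knockout vehicle replicates 1 or 3 or knockout GW4064 replicates 2 or 3 (adjusted p up to 0.475). The 17 FXR targets did not move in the knockout beyond the test's threshold (0 called over all genes and 0 adjusted over the list alone, camera adjusted p = 0.755, limma).

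Whether the agonist effect differs between the genotypes was tested as an interaction, wild-type change minus knockout change. The Slc51 pair, Tm4sf4 and B4galt5 were among the genes with a more positive change in wild type, with log2 differences of 3.83 ± 0.17 for Slc51a, 3.05 ± 0.18 for Slc51b, 4.01 ± 0.44 for Tm4sf4 and 2.39 ± 0.14 for B4galt5 (limma adjusted p = 1.3e-06, 1.0e-05, 8.7e-04 and 1.0e-05). Aifm2 was among them, at 0.76 ± 0.11 (adjusted p = 0.00484, limma), while Gpx4 was not (-0.08 ± 0.06, adjusted p = 0.52). In the opposite direction were Cyp26b1, a retinoic acid hydroxylase (-2.35 ± 0.29), Slc25a25 (-1.89 ± 0.35), Slc13a2 (-1.37 ± 0.26), and Pck1 (-1.30 ± 0.27). Cyp26b1 fell from 5.66 ± 0.21 to 1.36 ± 0.396 TPM in wild type and measured 11.3 ± 1.8 and 17.6 ± 4.56 TPM in the knockout.

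In all 462 genes passed the interaction test, 249 with a higher and 213 with a lower change in wild type (limma), and with median-of-ratios scaling these were 346 and 141. Others among the largest positive values were the vitamin D-degrading enzyme Cyp24a1 (2.17 ± 0.52), the urea cycle enzyme Ass1 (2.06 ± 0.35), Tstd2 (1.99 ± 0.14), Etnppl (1.84 ± 0.37), Misp3 (1.84 ± 0.21) and C3 (1.69 ± 0.29). Others among the largest negative values were Cck (-1.86 ± 0.39), the stress-response gene Nupr1 (-1.48 ± 0.28), the glutamine transporter Slc38a3 (-1.31 ± 0.25) and G0s2, an inhibitor of fat breakdown (-1.30 ± 0.25). Snora75 (-1.59 ± 0.27) and Mir365-2 (-1.49 ± 0.23) lie inside host transcripts, so their values are uncertain. The value of Ass1 is uncertain as well, because most reads of its locus were assigned to a second gene with the same span. Of the 360 genes higher and 336 lower in wild type, 204 and 131 also passed the interaction test, and 127 interaction genes had no call in wild type.

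Over all genes tested, the wild-type and knockout changes, which share no library, were correlated at r = -0.09 (Spearman's rho = -0.14). Genes are not independent replicates. The 360 genes higher with GW4064 in wild type had a knockout median of -0.01 against 0.48, and 162 were positive there. Among these were Abcc2 (0.30 ± 0.12), Gsr (0.26 ± 0.06), Rrm2 (0.30 ± 0.11) and Tfrc (0.25 ± 0.11). The 336 lower genes had 0.04 against -0.38, and 137, with Aqp2 (-0.28 ± 0.10), were negative. The interaction count was 216 and 295 without wild-type GW4064 replicates 1 and 2 in turn. It was 283 and 257 without wild-type vehicle replicates 1 and 3. It was 231 without knockout vehicle replicate 1 and 272 without knockout GW4064 replicate 3. With the fat marker score as a covariate it was 207. Slc13a2, Pck1, Cyp24a1, Etnppl, Cck and Nupr1 were not called with that score. The calls of Slc51a, Slc51b, Tm4sf4, B4galt5, Tstd2, Ass1, Misp3, C3, Cyp26b1, Slc25a25, Slc13a2 and Aifm2 held in each removal of a library. Of the other genes, 7 lost theirs when certain libraries were left out (limma). For Cyp24a1 these were all but wild-type vehicle replicates 2 and 3 (adjusted p up to 0.0996) and for Cck all but wild-type vehicle replicate 2, wild-type GW4064 replicate 3, knockout vehicle replicate 3 and knockout GW4064 replicate 2 (0.0757). For Pck1 they were all but wild-type vehicle replicate 1, wild-type GW4064 replicate 2, knockout vehicle replicate 2 and knockout GW4064 replicates 1 and 2 (0.0719). For Etnppl they were wild-type vehicle replicate 3, wild-type GW4064 replicates 1 and 2 and knockout vehicle replicate 1 (0.0608). Nupr1 lost its call without wild-type GW4064 replicate 1 or knockout vehicle replicate 1 (adjusted p up to 0.0525), Slc38a3 without the former and G0s2 without the latter (0.0501 and 0.0542, limma).

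**Figure D2:**
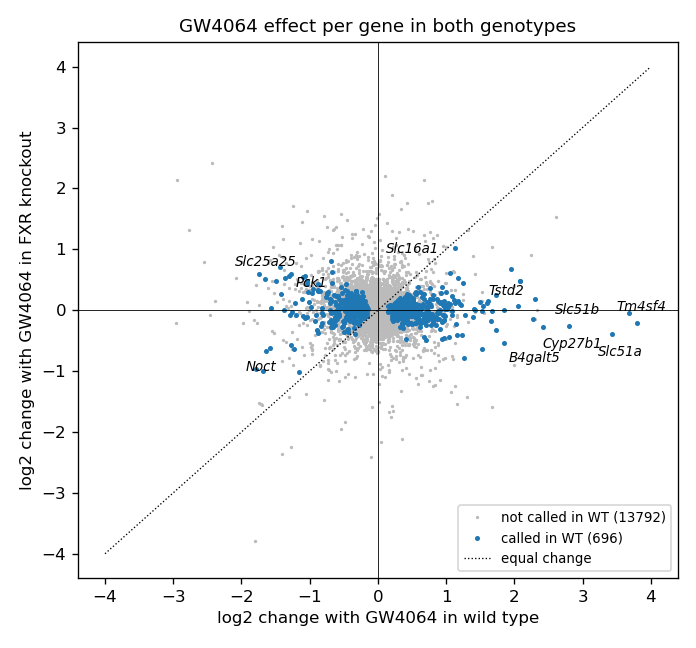
Log2 change with GW4064 per gene in wild type (horizontal axis) against the change in the FXR knockout (vertical axis) for 14488 genes, with the 696 called in wild type in blue, the others in grey and a dotted line at equal change. Slc51a (3.43 and -0.40), Slc51b (2.80 and -0.25) and Tm4sf4 lie far to the right.

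Lists that passed the interaction test upward, meaning a more positive change in wild type, were the bile acid and organic anion transporters and the FXR targets. Of the 18 transporters 2 rose (Slc51a, Slc51b) and 1 fell (Abcc4, -1.12 ± 0.17), and 2 and 2 did so adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.261 with an estimated correlation, limma). Of the 17 FXR targets the same pair rose and Kng1 fell (-2.14 ± 0.52), and 4 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0418, and adjusted p = 0.261 with an estimated correlation). Of 24 proximal tubule markers 4 rose and 1 fell, and 8 and 1 did so adjusted over the list alone (camera adjusted p = 1.9e-04, and adjusted p = 0.261 with an estimated correlation, limma). The 4 were Ass1, the sodium-glucose transporter Slc5a1 (0.53 ± 0.08), the endocytic receptor Cubn (0.30 ± 0.06) and Slc22a30 (0.50 ± 0.10), and Pck1 was the member that fell. Of 30 respiratory chain genes 1 rose, Cox5a (0.23 ± 0.06), also adjusted over the list alone (camera adjusted p = 9.8e-05, and adjusted p = 0.619 with an estimated correlation). The cell cycle list also moved up, with 0 of 22 members called over all genes and 0 adjusted over the list alone (camera adjusted p = 9.8e-05, and adjusted p = 0.704 with an estimated correlation). NRF2 targets moved down (0 rose and 7 fell of 23, 2 and 13 adjusted over the list alone, camera adjusted p = 0.00108, and adjusted p = 0.704 with an estimated correlation, limma), among them Srxn1 (-0.72 ± 0.11) and thioredoxin reductase Txnrd1 (-0.38 ± 0.09). The urothelial list moved down with 0 of 7 members called over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0065, and adjusted p = 0.704 with an estimated correlation). Quantile scaling ended the calls of the transporter, FXR target, proximal tubule and respiratory chain lists (adjusted p = 0.0876, 0.0839, 0.0762 and 0.227, limma camera). The FXR target call was lost without wild-type vehicle replicate 1, wild-type GW4064 replicate 2, knockout vehicle replicate 3 or knockout GW4064 replicate 2 (adjusted p = 0.0637, 0.0676, 0.0968 and 0.143). The libraries whose removal ended the call of Txnrd1 were all but wild-type GW4064 replicate 2 and knockout GW4064 replicate 2, and those for Kng1 all but knockout vehicle replicates 1, 2 and 3 (adjusted p up to 0.0984 and 0.118, limma). For Cubn they were wild-type vehicle replicates 1 and 2, wild-type GW4064 replicate 1, knockout vehicle replicates 1 and 3 and knockout GW4064 replicate 3, for Slc22a30 wild-type vehicle replicates 2 and 3, wild-type GW4064 replicates 2 and 3 and knockout GW4064 replicates 1 and 3, and for Cox5a all but knockout vehicle replicate 3 (up to 0.0766, 0.0573 and 0.117).

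The genotypes were then compared on vehicle. Genes of fatty acid use were prominent among the increases in the knockout. Pdk4, the kinase that restrains glucose oxidation, measured 68.3 ± 14.5 TPM in wild type and 455 ± 91.8 TPM in the knockout (log2 2.73 ± 0.24, adjusted p = 7.3e-05, limma, n = 3 per group). The fatty acid-binding protein Fabp1 (5.12 ± 1.45 and 31.2 ± 6.53 TPM, 2.51 ± 0.27), the lipid droplet protein Plin2 (139 ± 11.6 and 552 ± 144 TPM, 1.95 ± 0.16) and the peroxisomal oxidation enzyme Ehhadh (903 ± 26.7 and 2083 ± 176 TPM, 1.20 ± 0.09) were higher as well. Of 25 genes of the PPAR-alpha and fatty acid oxidation list, 18 rose and 1 fell over all genes, and 19 and 1 did so adjusted over the list alone. The member that fell was the coactivator gene Ppargc1a (-0.20 ± 0.05), whose call was lost with median-of-ratios and quantile scaling and without wild-type vehicle replicates 1 or 2 or knockout vehicle replicate 2 (adjusted p up to 0.0677, limma). The list moved up (camera adjusted p = 6.1e-25, limma), with adjusted p = 0.0708 with an estimated correlation.

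In all 1872 genes differed between the genotypes on vehicle, 462 higher and 1410 lower in the knockout (limma). This split depended on the scaling, with 833 higher and 539 lower for median-of-ratios factors and 674 higher and 591 lower for quantile normalization. Other genes with the largest increases were Cyp24a1 (2.62 ± 0.37), Apoh, an apolipoprotein (2.42 ± 0.33), Gas2l3 (2.29 ± 0.14), Slc16a1 (2.11 ± 0.10, 23 ± 1.59 and 101.1 ± 10.4 TPM), Cyp2a4 (2.01 ± 0.15) and the fatty acid hydroxylases Cyp4a12a (2.58 ± 0.23) and Cyp4a12b (1.99 ± 0.18). The largest decreases included the carboxylesterase Ces1g (-3.40 ± 0.26, 27.4 ± 6.95 and 2.16 ± 0.776 TPM), the lysophosphatidylcholine transporter Mfsd2a (-2.07 ± 0.44), the prolactin receptor Prlr (-1.86 ± 0.39), uridine phosphorylase Upp2 (-1.81 ± 0.42), the repressor Bcl6 (-1.60 ± 0.29), Plac9b (-1.49 ± 0.35) and the growth factor Igf1 (-1.41 ± 0.22). The Cyp4a12 pair, Cyp2a4 and Plac9b have near-identical copies, and their values are uncertain. The FXR-responsive Slc51a (-0.05 ± 0.12, adjusted p = 0.822) and Slc51b (0.30 ± 0.13, adjusted p = 0.146) did not pass on vehicle (limma). The count was 926 without wild-type vehicle replicate 3, 960 without wild-type vehicle replicate 1, 1155 without knockout vehicle replicate 1 and 1116 without knockout vehicle replicate 2. Mfsd2a and Prlr lost their calls without wild-type vehicle replicate 3, Upp2 without wild-type vehicle replicate 2, and Plac9b without wild-type vehicle replicates 1 or 3 or knockout vehicle replicate 1 (adjusted p up to 0.0542, 0.0521, 0.0524 and 0.0592, limma).

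Clock genes differed in both directions. The activator genes Arntl (BMAL1, 2.5 ± 0.767 TPM in wild type and 14.9 ± 3.29 TPM in the knockout, 2.37 ± 0.26) and Npas2 (1.73 ± 0.25), the repressor Cry1 (0.82 ± 0.13) and Nfil3 (1.74 ± 0.23) were higher in the knockout on vehicle. In contrast Nr1d1 (REV-ERB-alpha, 22.3 ± 6.27 and 2.61 ± 1.31 TPM, -2.92 ± 0.33), Dbp (114 ± 24 and 18.2 ± 4.9 TPM, -2.62 ± 0.26), Ciart (-2.63 ± 0.31) and Tef (-0.80 ± 0.07) were lower. Of 18 clock genes 4 rose and 7 fell, and 5 and 10 did so adjusted over the list alone. With members on both sides the list did not pass camera (adjusted p = 0.362, limma, and adjusted p = 0.626 with an estimated correlation). The labels give no time of collection.

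Several cell type lists passed at the preset correlation. Of 16 immune cell genes 8 were higher in the knockout on vehicle and 12 adjusted over the list alone, with the class II antigen presentation genes H2-Ab1 (0.92 ± 0.19) and H2-Eb1 (0.73 ± 0.15) among them (camera adjusted p = 6.8e-10, and adjusted p = 0.0708 with an estimated correlation, limma). Of 18 extracellular matrix genes 10 fell, and 1 rose and 12 fell adjusted over the list alone, with the basement membrane collagens Col4a1 (-0.65 ± 0.05) and Col4a2 (-0.63 ± 0.05) at the lowest p (camera adjusted p = 1.4e-04, and adjusted p = 0.321 with an estimated correlation). Of 10 podocyte genes 7 fell over all genes and 7 adjusted over the list alone, among them Podxl (-0.28 ± 0.06) (camera adjusted p = 0.00589, and adjusted p = 0.253 with an estimated correlation, limma). Of 14 endothelial genes 5 fell over all genes and 7 adjusted over the list alone, including Emcn (-0.47 ± 0.09) and Tek (-0.30 ± 0.06) (camera adjusted p = 0.0293, and adjusted p = 0.334 with an estimated correlation). The endothelial call was lost with median-of-ratios and quantile scaling (adjusted p = 0.0604 and 0.0569) and without wild-type vehicle replicate 3 or knockout vehicle replicates 2 or 3 (adjusted p = 0.0664, 0.0855 and 0.0647, limma camera). Of 16 glucocorticoid-responsive genes 4 rose over all genes and 4 adjusted over the list alone, including the kinase gene Sgk1 (1.61 ± 0.19) and the cell cycle inhibitor Cdkn1a (1.58 ± 0.15) (camera adjusted p = 1.2e-06, and adjusted p = 0.201 with an estimated correlation).

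Among ferroptosis genes on vehicle, Acsl4 (Entrez Gene 50790, chromosome X, 142317993 to 142390535) was higher in the knockout, at 68.3 ± 1.76 TPM in wild type and 113 ± 19.7 TPM in the knockout (log2 0.70 ± 0.09, adjusted p = 8.9e-04, limma, n = 3 per group). Of 24 ferroptosis driver genes 3 rose and 4 fell over all genes, and 3 and 4 did so adjusted over the list alone (camera adjusted p = 0.144, limma, and adjusted p = 0.313 with an estimated correlation). The others were Lpcat3 (0.16 ± 0.05) and Pebp1 (0.13 ± 0.04) upward, and Slc1a5 (-0.34 ± 0.06), the transferrin receptor Tfrc (-0.57 ± 0.11), Vdac2 (-0.13 ± 0.04) and Ireb2 (-0.16 ± 0.03) downward. Of 26 suppressors 4 rose, namely ferritin light chain Ftl1 (0.41 ± 0.08), Nfe2l2, the gene of NRF2 (0.21 ± 0.05), Txnrd1 (0.33 ± 0.06) and Acsl3 (0.19 ± 0.06). The 3 that fell were Gsr (-0.21 ± 0.06), glutathione synthetase Gss (-0.23 ± 0.05) and Mboat2 (-0.44 ± 0.12). Adjusted over the list alone 4 rose and 3 fell, and the list moved up (camera adjusted p = 0.0014, and adjusted p = 0.3 with an estimated correlation, limma), a call that quantile scaling ended (adjusted p = 0.0965). Gpx4 (0.06 ± 0.05) and Aifm2 (0.07 ± 0.08) did not pass (adjusted p = 0.42 and 0.558, limma). Gsr, Gss, Mboat2, Vdac2 and Ireb2 were not called with median-of-ratios scaling, nor Ftl1, Gsr, Mboat2, Ireb2 and Pebp1 with quantile scaling. The libraries whose removal ended the call of Acsl3 were all but knockout GW4064 replicates 1 and 3, of Gsr all but knockout vehicle replicate 2 and knockout GW4064 replicates 1 and 2, of Lpcat3 all but knockout vehicle replicate 1, of Pebp1 all but knockout GW4064 replicate 1 and of Vdac2 all but wild-type vehicle replicate 2, knockout vehicle replicate 1 and knockout GW4064 replicates 1, 2 and 3 (adjusted p up to 0.136, 0.127, 0.156, 0.158 and 0.121, limma). Nfe2l2 lost its call without any of the 3 wild-type vehicle libraries or knockout vehicle replicate 2, Mboat2 without wild-type vehicle replicates 1 or 3 or knockout vehicle replicates 1 or 2, and Gss without wild-type vehicle replicates 1 or 3 (adjusted p up to 0.0844, 0.0997 and 0.0545, limma).

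Of the 15 tubule injury markers 3 were higher in the knockout on vehicle, Cdkn1a, Tnfrsf12a (1.26 ± 0.17) and Il34 (0.69 ± 0.20), and 3 lower, Krt8 (-0.28 ± 0.05), Plau (-0.22 ± 0.06) and Cryab (-0.88 ± 0.20). Adjusted over the list alone these were 3 and 3, and the list did not pass (camera adjusted p = 0.109, limma, and adjusted p = 0.464 with an estimated correlation). It passed without wild-type vehicle replicate 1 or knockout vehicle replicate 1 (adjusted p = 0.0482 and 0.0261). Under GW4064 Cdkn1a (2.09 ± 0.15), Tnfrsf12a (1.30 ± 0.17) and Il34 (0.68 ± 0.20) were higher and Plau (-0.37 ± 0.06) lower, and 4 were higher and 1 lower adjusted over the list alone. The list moved up there (camera adjusted p = 0.043, and adjusted p = 0.36 with an estimated correlation, limma). That call was lost with median-of-ratios or quantile scaling (adjusted p = 0.0882 and 0.0671), with protein-coding genes only, and without wild-type GW4064 replicate 2 or knockout GW4064 replicate 1 (0.0505 and 0.1). In the interaction Cryab was the only marker called (-1.19 ± 0.28), with 0 and 1 adjusted over the list alone, and of the 24 ferroptosis drivers Slc1a5 was (-0.56 ± 0.08). On vehicle Il34 lost its call without any library but wild-type GW4064 replicates 2 and 3, knockout vehicle replicate 1 and knockout GW4064 replicate 2. Plau lost it without wild-type vehicle replicates 2 and 3, wild-type GW4064 replicate 2 and knockout vehicle replicates 1, 2 and 3 and Cryab without wild-type vehicle replicates 1 and 3 and knockout vehicle replicate 2 (adjusted p up to 0.14, 0.122 and 0.0604). Under GW4064 Il34 lost it without wild-type GW4064 replicates 1 and 2 and knockout GW4064 replicates 1 and 2, and in the interaction Cryab did so without any library but wild-type vehicle replicate 2 and knockout GW4064 replicate 2 (0.116 and 0.113, limma). Median-of-ratios scaling ended the call of Plau on vehicle and that of Cryab in the interaction.

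The genotypes were last compared under GW4064, where the agonist response and the genotype act together. Among the largest decreases in the knockout were those of Tm4sf4 (-4.29 ± 0.31), Slc51a (-3.87 ± 0.12), Cyp27b1 (-3.09 ± 0.56), Fgb (-2.93 ± 0.22), Slc51b (-2.76 ± 0.13), B4galt5 (-2.48 ± 0.10) and Etnppl (-2.37 ± 0.26). Ces1g (-3.11 ± 0.26), Dbp (-2.89 ± 0.26) and Nat8f3 (-2.81 ± 0.88) were also lower. Higher in the knockout were Cyp26b1 (3.27 ± 0.20), Slc16a1 (2.81 ± 0.10, 23.9 ± 3.22 and 169.7 ± 9.24 TPM), Fabp1 (2.73 ± 0.27), Arntl (2.55 ± 0.26), Pdk4 (2.41 ± 0.24), Apoh (2.28 ± 0.33), Plin2 (2.23 ± 0.16) and the cytochrome P450 genes Cyp4a14 (2.73 ± 0.22), Cyp2a4 (2.48 ± 0.15) and Cyp4a32 (2.23 ± 0.44). In all 2677 genes differed, 1026 higher and 1651 lower in the knockout (limma), and 1251 higher and 1309 lower with median-of-ratios scaling. Without wild-type GW4064 replicate 1 there were 1726. Nat8f3, and the Cyp4a and Cyp2a genes, have close paralogs and are uncertain, and Nat8f3 lost its call without any library outside knockout GW4064 (adjusted p up to 0.12, limma). Its log2 change was -1.34 without knockout GW4064 replicate 2.

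Fatty acid genes again stood out under GW4064, with 21 of 25 PPAR-alpha and fatty acid oxidation genes higher and 1 lower (Ppargc1a, -0.31 ± 0.05) in the knockout, and the same numbers adjusted over the list alone (camera adjusted p = 8.0e-18, and adjusted p = 0.288 with an estimated correlation, limma). Ehhadh was at 1018 ± 123 and 2580 ± 265 TPM (1.34 ± 0.09). Of 23 NRF2 targets 14 were higher, among them Srxn1 (1.11 ± 0.08), Txnrd1 (0.71 ± 0.06) and the quinone reductase Nqo1 (1.00 ± 0.13), and 3 were lower, Osgin1 (-1.68 ± 0.27), Gsr (-0.37 ± 0.06) and Gclm (-0.31 ± 0.05). Adjusted over the list alone 15 were higher and 3 lower (camera adjusted p = 7.0e-07, and adjusted p = 0.339 with an estimated correlation). Of 18 clock genes 5 were higher, including Npas2 (2.52 ± 0.25), and 8 lower, including Tef (-0.95 ± 0.07) and Nr1d2 (-1.35 ± 0.11). Adjusted over the list alone these were 5 and 9 (camera adjusted p = 0.178, not passed, and adjusted p = 0.475 with an estimated correlation, limma). The clock list passed without knockout GW4064 replicate 2 (adjusted p = 0.0412). Of 22 cell cycle genes 7 were lower, Mcm6 (-0.54 ± 0.11) and Mki67 (-1.09 ± 0.24) among them, and 8 adjusted over the list alone (camera adjusted p = 0.00145, and adjusted p = 0.446 with an estimated correlation).

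**Figure D3:**
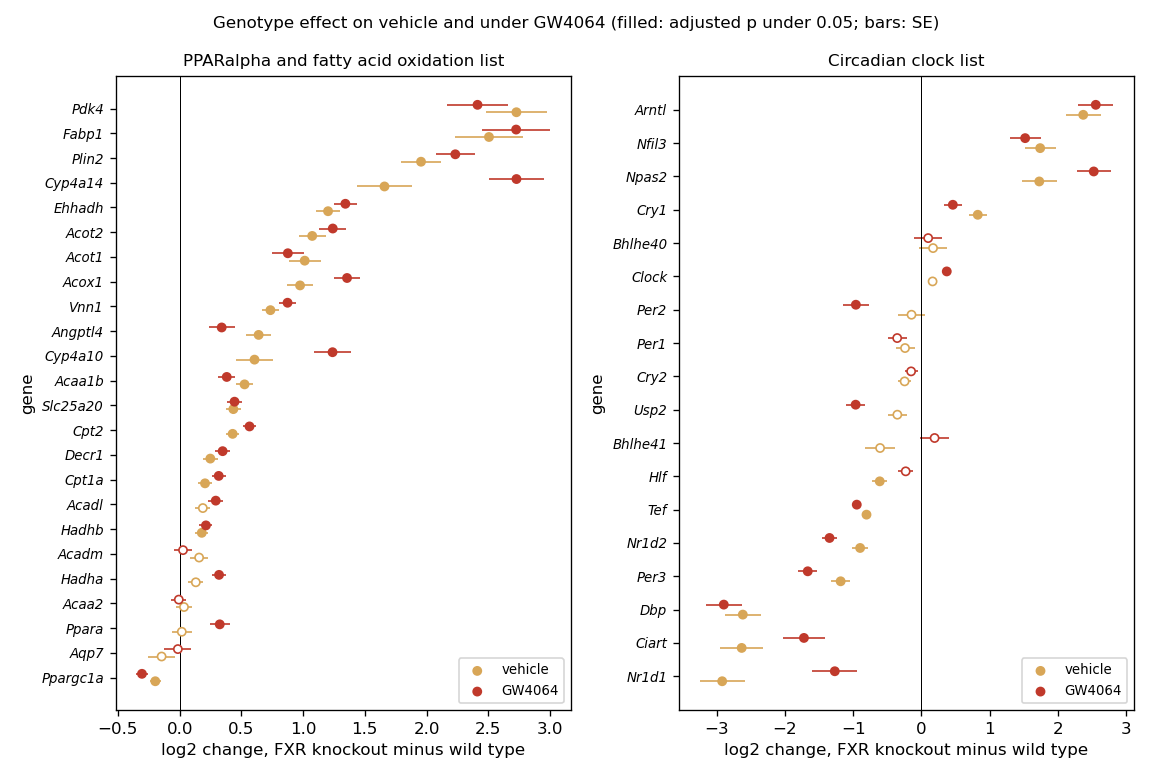
Log2 change, knockout minus wild type (horizontal axis), for 24 of the 25 tested genes of the PPAR-alpha and fatty acid oxidation list and all 18 of the circadian clock list (vertical axis), in ochre for vehicle and red for GW4064, where bars are standard errors and filled points passed the limma test at an adjusted p under 0.05. Most fatty acid genes lie right of 0 in both treatments (18 and 21 of all 25 called higher), while clock genes lie on both sides.

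For ferroptosis under GW4064, Aifm2 was lower in the knockout (38.5 ± 2.74 TPM in wild type, 23.7 ± 0.943 TPM in the knockout, -0.69 ± 0.08, adjusted p = 1.3e-04), and Acsl4 was higher (56.1 ± 0.807 and 121 ± 5.13 TPM, 1.10 ± 0.09, adjusted p = 1.2e-05, limma). Fth1 was also higher (2588 ± 152 and 3590 ± 206 TPM, 0.47 ± 0.08, adjusted p = 0.00252), and Gpx4 lay at the threshold (0.14 ± 0.05, adjusted p = 0.0511, limma), which it passed with median-of-ratios scaling (adjusted p = 0.0333), without wild-type vehicle replicate 1 (0.0459) and without knockout GW4064 replicate 2 (0.0433). Of 26 suppressors 8 were higher and 6 lower, and 12 and 6 adjusted over the list alone, with glutathione synthetase Gss (-0.30 ± 0.05) among the lower. The list moved up (camera adjusted p = 0.0451, and adjusted p = 0.414 with an estimated correlation, limma), a call that ended with median-of-ratios or quantile scaling (adjusted p = 0.0612 and 0.145) and without wild-type GW4064 replicate 3 or knockout GW4064 replicate 1 (0.0851 and 0.069). Of 24 drivers 4 were higher (Acsl4, Lpcat3 at 0.24 ± 0.05, heme oxygenase Hmox1 at 1.40 ± 0.29, Slc1a5 at 0.22 ± 0.06) and 5 lower, and 5 and 8 adjusted over the list alone (camera adjusted p = 0.591, limma, and adjusted p = 0.627 with an estimated correlation). The 5 lower drivers were Tfrc (-0.79 ± 0.11), Ireb2 (-0.20 ± 0.03), Far1 (-0.19 ± 0.06), Slc39a14 (-0.31 ± 0.06) and Agps (-0.25 ± 0.07). Slc1a5 lost its call without any of the 3 wild-type GW4064 libraries or knockout GW4064 replicates 2 or 3 (adjusted p up to 0.0769, limma). Far1 lost its call without wild-type GW4064 replicates 1 and 3 and knockout GW4064 replicates 1 and 3, and Agps without wild-type GW4064 replicates 2 and 3 and knockout GW4064 replicates 1 and 3 (up to 0.148 and 0.0822), and neither was called with quantile scaling.

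Of the 17 FXR targets under GW4064, 2 were higher in the knockout (Kng1 at 1.41 ± 0.37 and Pdk4) and 5 lower (Slc51a, Slc51b, Osgin1, Ddah1 at -0.22 ± 0.05 and the bile acid conjugating enzyme Baat at -0.66 ± 0.16), and 2 and 7 adjusted over the list alone (camera adjusted p = 0.0946, not passed, and adjusted p = 0.339 with an estimated correlation, limma). Of 10 fat markers 3 were higher (Lipe at 0.80 ± 0.14, the proximal tubule gene Pck1 at 1.04 ± 0.19, Pnpla2 at 0.58 ± 0.16), and 3 adjusted over the list alone, and the list moved up (camera adjusted p = 0.00298, and adjusted p = 0.339 with an estimated correlation), a call lost with the fat marker score as a covariate (adjusted p = 0.0721). Without wild-type GW4064 replicates 1 and 2 and knockout GW4064 replicates 2 and 3 in turn the call of Kng1 was lost, and without wild-type GW4064 replicates 1, 2 and 3 and knockout GW4064 replicates 2 and 3 that of Pnpla2 (adjusted p up to 0.0645 and 0.104, limma). Baat lost its call without wild-type GW4064 replicate 3 and knockout GW4064 replicate 3 (up to 0.0607). The genotype effects on vehicle and under GW4064, which share no library, were correlated at r = 0.36 (Spearman's rho = 0.34) across genes. In both, 287 genes were higher (32.7 if the lists were independent), 562 were lower (161 if independent) and 29 were called in opposite directions. Both comparisons use the same variance estimate of each gene, so their calls are not independent and these numbers are only a reference.

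The GW4064 effect in wild type and the genotype effect on vehicle share the wild-type vehicle libraries. Their log2 changes were correlated at r = 0.40 across genes, against a mean of 0.50 in 100 simulations of unchanged groups with the same controls. The covariance was 0.0382, against a simulated mean of 0.0232 (SD 0.00204). Of the calls, 54 genes were higher in both (11.5 if independent) and 108 lower in both (32.7), while 55 were higher with GW4064 and lower in the knockout (35.0) and 15 the reverse (10.7). With 3 control libraries the controls could not be split into sets of at least 2, so part of the excess called in the same direction may come from the shared controls. Shared controls push both changes the same way and so do not account for the numbers in opposite directions. The variance estimate of each gene is also shared, which the numbers under independence leave out. Bcl6 was among the genes lower in both comparisons.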

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

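The tests of explanations below were all chosen after the result was seen, while the counts of other splits and relabelings were planned. The results here came up because the change with GW4064 differed between wild type and knockout in a test of the difference itself (limma, interaction, n = 3 per group). They are 462 genes and 7 gene lists. The log2 differences, wild-type change minus knockout change, were 4.01 for Tm4sf4, 3.83 for Slc51a, 3.05 for Slc51b, 2.39 for B4galt5, 2.17 for Cyp24a1, 2.06 for Ass1, 1.99 for Tstd2, 1.84 for Etnppl, 1.84 for Misp3, 1.69 for C3, 0.76 for Aifm2, 0.53 for Slc5a1, 0.30 for Cubn, 0.50 for Slc22a30 and 0.23 for Cox5a. Negative differences were -2.35 for Cyp26b1, -1.89 for Slc25a25, -1.86 for Cck, -1.59 for Snora75, -1.49 for Mir365-2, -1.48 for Nupr1, -1.37 for Slc13a2, -1.31 for Slc38a3, -1.30 for G0s2, -1.30 for Pck1, -0.38 for Txnrd1, -1.12 for Abcc4, -0.72 for Srxn1, -2.14 for Kng1, -0.56 for Slc1a5 and -1.19 for Cryab. At the preset correlation the camera adjusted p was 0.0418 for FXR targets and 0.0118 for bile acid and organic anion transport, both upward. Also upward were the proximal tubule (1.9e-04), the respiratory chain (9.8e-05) and the cell cycle (9.8e-05). NRF2 targets (0.00108) and the urothelium (0.0065) moved downward. With an estimated correlation 0 lists were called in the interaction.

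Of 100 relabelings drawn from 200, 1 (the real one) gave as many interaction genes as the 462 found, and the highest other gave 228. The 8 others that kept the real split of the wild-type libraries gave 142 to 228, and the 91 that did not, and so lost the wild-type effect itself, gave 0 to 2. Only 20 relabelings exist that keep it, too few for a share under 0.05. For lists, 28 of 100 relabelings gave at least the 7 called (highest other 10), so chance cannot be excluded for the number of lists. For the other comparisons only 10 splits exist, too few for a share under 0.05. Genes called numbered 696 for GW4064 in wild type (as many in 1 split, highest other 1), 2 for GW4064 in the knockout (as many in 4 splits, highest other 2), 1872 for the genotypes on vehicle (as many in 1 split, highest other 1) and 2677 under GW4064 (as many in 1 split, highest other 4). Lists called numbered 5 (as many in 3 splits, highest other 6), 7 (as many in 4 splits, highest other 13), 14 (as many in 1 split, highest other 12) and 14 (as many in 1 split, highest other 13).

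With GW4064, 696 genes were called in wild type and 2 in the knockout. A larger spread between knockout libraries would leave the wild-type changes in place there. The genes called higher in wild type had a median knockout change of -0.0118 against 0.48, and those called lower 0.04 against -0.38. Medians near 0 do not show that no gene moved there. In the knockout 71 of the 360 higher and 93 of the 336 lower genes had an unadjusted p under 0.05 (limma), in either direction. Over all 14488 genes 1560 did. Wild-type vehicle libraries standing apart from the other 9 would shift the same genes between genotypes on vehicle. The genes called higher had a median genotype change of 0.00385 there, which argues against it for that set as a whole. This median does not speak on a smaller part of the set. Of the 360, 54 were also called higher in the knockout on vehicle (11.5 if independent) and 55 lower (35.0). The genes called lower with GW4064 had a median of -0.16 against -0.38. The median over all 14488 genes was -0.087, and both sets were selected with the same wild-type vehicle libraries, which shifts both changes the same way. For the lower genes the test therefore cannot decide. Fat left on some kidneys would shrink the changes once a fat marker score is fitted. Over the 696 genes the median ratio of the changes with and without it was 1.002. This median does not speak on fat as a cause for a smaller set of genes. The standard errors grew by a median ratio of 1.147, so the lower count of 428 with the score came with wider errors. Time of collection, which the labels do not give, was not tested for this pattern. In wild type Nr1d1 measured 22.3 ± 6.27 TPM on vehicle and 9.54 ± 2.23 TPM with GW4064, and Arntl 2.5 ± 0.767 and 3.56 ± 1.00 TPM. In the knockout Nr1d1 measured 2.61 ± 1.31 and 3.81 ± 1.55 TPM, and Arntl 14.9 ± 3.29 and 23.6 ± 7.65 TPM. Tef was lower with GW4064 in both genotypes (260 ± 6.22 and 225 ± 8.85 TPM in wild type, 149 ± 14.5 and 117 ± 7.43 TPM in the knockout). No clock gene was called with GW4064 in the knockout (limma). A response that needs FXR remains a hypothesis beside these.

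More genes were lower (1410) than higher (462) in the knockout on vehicle. With median-of-ratios factors 60.7% of calls were higher, against 24.7% with TPM. These factors bring the median log2 change from -0.087 to -0.0046, which shifts the balance of calls by itself, so the scaling of TPM to a fixed total cannot be told apart from a true excess of decreases. The direction of the majority is left open. No biological explanation was tested.

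Between the genotypes 848 genes were called the same way on vehicle and under GW4064, apart from Nr1h4 itself. A chromosome segment from the donor strain may account for part of the genes near Nr1h4. Of 56 genes within 5 Mb, 13 were called so (23.2% against 5.79% elsewhere, one-sided Fisher's exact p = 1.56e-05). Position cannot tell whether the segment acts on the 96.3% of the 848 over 20 Mb away or on other chromosomes. A different clock phase stays open, as 10 clock genes were called the same way (4 higher, 6 lower) and the time of collection, which the labels do not give, cannot be told apart from genotype. A strain difference also stays open, because Nnt, which is partly deleted in some C57BL/6 substrains, had a log2 difference of -1.14 on vehicle and -1.22 under GW4064. Loss of FXR is untested against these, since each knockout library shares them.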

How the results depend on the processing

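Restriction to protein-coding genes and the fat marker score were chosen after seeing the data, and the other alternatives were planned before the data were examined. The level of Nr1h4 on vehicle kept its direction and call in all 14 alternatives (log2 -1.07 to -0.98) and without each library (-1.14 to -0.995). Counts of genes lay within 1.5 times the main count in all 14 alternatives for the genotypes on vehicle (1265 to 2197, main 1872) and under GW4064 (2112 to 2808, main 2677), in 13 of 14 for GW4064 in wild type (428 to 938, main 696) and in 12 of 13 for the interaction (207 to 556, main 462). A gene named in several comparisons counts once in each. Of the calls of named genes, 31 of 48 for GW4064 in wild type, 0 of 2 in the knockout, 50 of 64 for the genotypes on vehicle, 51 of 57 under GW4064 and 19 of 31 in the interaction were kept in each alternative. Without each library in turn 28, 0, 46, 49 and 18 were kept. Over the named genes and their alternatives, 2921 values kept direction and side of the threshold, 186 kept direction and lost the call, 7 gained a call and 4 changed sign, none of the last with a call before or after. Named calls lost in at least 1 alternative, with the number of alternatives, were Cyp27b1 (5), Cck (1), Bcl6 (4), Aqp2 (1), Kng1 (8), Top2a (1), Ccna2 (2), Mki67 (4), Slc40a1 (1), Pdss2 (4), Prom2 (1), Fga (5), Cxcl1 (3), Socs3 (6), Tfrc (2), Plau (2) and Cryab (2) for GW4064 in wild type, Slc16a1 (8) and Trim7 (3) in the knockout, Ppargc1a (3), Lpcat3 (6), Pebp1 (7), Vdac2 (5), Ireb2 (3), Ftl1 (1), Nfe2l2 (2), Acsl3 (6), Gsr (7), Gss (1), Mboat2 (4), Zfp36 (5), Il34 (6) and Plau (7) for the genotypes on vehicle, Nat8f3 (7), Slc1a5 (1), Far1 (4), Agps (3), Pnpla2 (1) and Il34 (2) under GW4064 and Slc13a2 (1), Pck1 (3), Cyp24a1 (6), Etnppl (1), Cck (2), Nupr1 (1), Kng1 (8), Cubn (3), Slc22a30 (2), Cox5a (5), Txnrd1 (5) and Cryab (5) in the interaction. For lists, 565 values kept their side of the threshold, 51 lost the call and 1 changed direction, that of ferroptosis drivers in wild type with quantile normalization (adjusted p = 0.9884), without a call. Leaving out 1 library gave that list 0.4225 to 0.9945, the last, without wild-type vehicle replicate 1, also in the other direction. The cause was not tested except where stated. Depth of 14.1 to 21.2 M (mega) read pairs limits genes at a few TPM, and changes of 0.5 on the log2 scale were recovered in 56.6% to 59.4% of simulated genes.

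With the fat marker score as a covariate, genes called were 428 for GW4064 in wild type and 207 for the interaction, lists under GW4064 were 9, and the correlation of the GW4064 effects was -0.12 (-0.1235), with wider standard errors for the wild-type count. In the interaction the score also ended the calls of Kng1, Cubn, Slc22a30, Cox5a, Txnrd1 and the urothelial list. With an estimated correlation, lists called were 0 in GW4064 in wild type, 0 in GW4064 in the knockout, 0 on vehicle, 0 under GW4064 and 0 in the interaction. With a filter of 5 TPM, which leaves fewer genes, lists called were 2 for GW4064 in wild type, 9 for the genotypes under GW4064 and 4 for the interaction. With quantile normalization they were 3 for GW4064 in wild type, 7 for the genotypes on vehicle and 3 for the interaction. Lists were 2 for GW4064 in wild type without the variance trend. For the genotypes under GW4064 they were 8 with median-of-ratios scaling, 9 with only the groups compared and 9 with protein-coding genes only. The 2 genes called for GW4064 in the knockout became 1 with a pseudocount of 0.1, 1 with median-of-ratios scaling, 1 with quantile normalization, 1 with sample weights, 0 with only the groups compared, 0 without the variance trend and 0 with the replicate block. The correlation of the GW4064 effects was -0.153 with protein-coding genes only. Log2 values changed sign for Gpx4 in wild type with median-of-ratios scaling (0.00518), for Slc51a on vehicle with median-of-ratios scaling (0.037) and quantile normalization (0.0213), and for Gpx4 on vehicle with quantile normalization (-0.0639). The cause was not tested.

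Leaving out 1 library gave 334 to 768 genes and 5 to 7 lists for GW4064 in wild type, 0 to 51 genes and 6 to 11 lists for GW4064 in the knockout, 926 to 1903 genes and 10 to 18 lists for the genotypes on vehicle, 1726 to 2760 genes and 9 to 20 lists under GW4064, and 216 to 535 genes and 6 to 8 lists for the interaction. The knockout gave 11 lists without knockout vehicle replicate 3, and the genotypes under GW4064 gave 9 without wild-type GW4064 replicate 3. The correlation ranged from -0.125 to -0.0429. Single log2 values that crossed 0 ranged from -0.0511 to 0.00782 for Gpx4 and -0.349 to 0.173 for Lcn2 in wild type, and from -0.148 to 0.0694 for Slc51a and -0.00802 to 0.121 for Aifm2 on vehicle. Fewer samples are part of each such change. A block by replicate number gave 675, 0, 1785, 2633 and 442 genes in the order of the comparisons above and 5, 6, 13, 16 and 7 lists. Replicate numbers did not pair the samples (18 pairs, r of residuals -0.0748 to 0.0829, 0 over 0.1), and 3 of 12 samples correlated best with a sample of their own number. Tests for counts and removal of mitochondrial genes could not be run, as the tables hold neither, and robust variance was not run for lists.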

Other observations

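The comparisons, the lists and the removal of single libraries used in this part were planned. Some of the genes, the fat marker score and the genes on shared loci were chosen after values were seen. Some lipid genes other than those of fatty acid oxidation also differed with GW4064 in wild type. Of 24 cholesterol synthesis genes, 1 rose, the isomerase Idi1 (0.59 ± 0.07), and 4 fell, among them Hsd17b7 (-0.43 ± 0.07) and Sqle (-0.38 ± 0.07), and 3 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.77, and adjusted p = 0.822 with an estimated correlation, limma). Of 18 fatty acid synthesis genes, Pnpla3 (1.21 ± 0.20, 0.703 ± 0.155 to 2.29 ± 0.512 TPM) and Elovl6 (0.49 ± 0.09) rose and Lpin1 fell, and 3 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.712, and adjusted p = 0.822 with an estimated correlation). Of 14 inflammation genes, C3, Fgb and the other fibrinogen gene Fga (1.17 ± 0.29) rose, while the chemokine Cxcl1 (-1.57 ± 0.36) and Socs3 (-0.59 ± 0.14) fell, and 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.712, upward with a median of -0.19 and a mean of 0.10, and adjusted p = 0.822 with an estimated correlation). Fga lost its call without wild-type vehicle replicates 1 and 3, wild-type GW4064 replicates 1 and 2 and knockout vehicle replicate 3 and Cxcl1 without wild-type vehicle replicates 1, 2 and 3 and wild-type GW4064 replicates 1 and 2 (adjusted p up to 0.137 and 0.118). The libraries whose removal ended the call of Socs3 were all but knockout vehicle replicates 1, 2 and 3 and knockout GW4064 replicate 1 (up to 0.133).

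Further lists passed between the genotypes on vehicle at the preset correlation. Of 18 immediate early genes 6 were higher in the knockout, with Klf6 (0.61 ± 0.06) and Myc (0.93 ± 0.19) among them, and 1 lower, Zfp36 (-0.33 ± 0.09), and 7 and 2 were so adjusted over the list alone (camera adjusted p = 6.6e-06, and adjusted p = 0.0708 with an estimated correlation, limma). Of 15 genes known to differ between male and female kidneys 5 were higher (Cyp2a4, Cyp4a14 at 1.66 ± 0.22, Cyp4b1 at 0.52 ± 0.09, Cyp7b1 at 1.22 ± 0.17 and Gstp1 at 0.25 ± 0.06) and 1 lower (Prlr), and 7 and 2 were so adjusted over the list alone (camera adjusted p = 1.6e-04, and adjusted p = 0.0708 with an estimated correlation), a call that quantile scaling ended (adjusted p = 0.0575). Zfp36 lost its call without wild-type vehicle replicates 2 and 3, wild-type GW4064 replicate 2 and knockout vehicle replicates 1 and 2, and Gstp1 without wild-type vehicle replicates 1 and 2 and knockout vehicle replicates 2 and 3 (adjusted p up to 0.117 and 0.0582), and Zfp36 was not called with median-of-ratios or quantile scaling. The Y-linked gene Ddx3y was at 69.9 ± 2.64, 74.6 ± 1.78, 72.2 ± 2.9 and 74.5 ± 4.96 TPM in wild-type vehicle, wild-type GW4064, knockout vehicle and knockout GW4064 libraries.

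Reads of the Ass1 locus were mostly assigned to Gm5424, a gene with the same span. Ass1 measured 3.33 to 16.0 TPM per library and Gm5424 1577 to 4374 TPM. Their sum was 2051 ± 98.9 TPM in wild-type vehicle, 4039 ± 304 TPM in wild-type GW4064, 2491 ± 48.9 TPM in knockout vehicle and 1820 ± 302 TPM in knockout GW4064 libraries (SD, n = 3 each). The sum rose with GW4064 in wild type (log2 0.98, limma adjusted p = 0.00018), and the interaction was 1.44 (adjusted p = 0.000283). Globin genes traded places between libraries, with Hba-a1 at 907.5 TPM and Hba-a2 at 1.82 TPM in wild-type GW4064 replicate 2 and Hba-a2 far above Hba-a1 in the other 11 libraries. Hbb-bs was far above Hbb-b1 in wild-type vehicle replicates 1 and 3 and knockout GW4064 replicate 3, and far below it in the other 9. A total of 416 pairs of genes share at least 95% of their span, with 330 genes in them, of which 69 were tested.

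Fat marker scores in the knockout were 1.83, 0.24 and 2.43 on vehicle and 2.49, 1.07 and 2.44 with GW4064. Cfd, an adipocyte gene, was at 17 ± 5.38 TPM in wild-type vehicle and 9.78 ± 13.5 TPM in wild-type GW4064 libraries, and the urothelial genes Upk3a and Psca were at 8.3 ± 0.4 and 18.5 ± 0.849 TPM in the former and 3.79 ± 0.681 and 8.22 ± 0.413 TPM in the latter.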
